A study of Mus musculus with 34 samples.

How the data were processed

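Bulk RNA-seq was examined in 34 mouse libraries: 15 of muscle stem cells (MuSCs), 7 of RORγ+ Tregs, 6 of whole muscle and 6 of whole liver, in 11 groups of 3 libraries, or 4 for muscle Tregs. Per the labels' protocols, sorted MuSCs went in batches of 1000 into lysis buffer, whole tissue gave RNA by Trizol, and libraries were made from polyadenylated RNA. No cell number was recorded here for the Treg libraries. The deposited table holds raw read counts per gene symbol, 55011 gene rows, which the authors made with STAR 2.7.3a and featureCounts on mm10, per the submitters' processing notes. Annotation, strand setting and filters are not given in the sources used here. Values were checked to be whole numbers with a different total in each library, all columns matched a sample (0 left over), and 45970 rows held a count. Of the symbols, 52936 are in GENCODE M21, with 99.4% of counts, which gave the coordinates. Pairs of replicates were tested for copies: the chi-square per degree of freedom ran from 1.67 to 27.6, so no pair differed by counting error alone.

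Each comparison was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, a quasi-likelihood fit with a term for group only, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. MuSC contrasts share a fit of all 15 libraries, Tregs, muscle and liver have their own fits, and the liver and muscle effects were compared in a fit of the 12 tissue libraries over genes that pass the filter in both. CPM (counts scaled to the library total) are means and SD of libraries. Log2 changes come from the TMM-scaled fit, so a ratio of CPM need not equal the fold. Folds against a group with no count use a floor of 3 counts over the group and allow for counting error only. Leaving out a library of that group raises the floor, which leaves 0.627 to 0.808 of the bound. The total count of each library sets the precision: in the day 3 PBS group, at 733202 to 791937 counts, a gene at 10 CPM has fewer than 8 counts per library.

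Gene lists, the tests, the alternatives and the rule for named genes were written before the data were examined. Lists with at least 5 tested members were tested with limma 3.58.1 (camera, preset correlation of 0.01, Benjamini-Hochberg over the lists of a comparison), and again with an estimated correlation and with fry. The rule names, per comparison, the called genes with the 10 largest and 10 smallest log2 changes among those with a mean of at least 10 CPM, TMM-scaled, in the higher group and no overlap between the groups' libraries. It leaves out predicted genes, pseudogenes, small RNA, mitochondrial, ribosomal protein and antigen receptor segment genes. It adds the first members of each list by p, Maf, Rorc, Foxp3, Il17a, Il17ra and Il17rc, the genes of the sorting gate, and, where a direction holds no such gene, the 5 with the smallest p, as not passing. Genes outside it are marked as picked after their values were seen.

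Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, mitochondrial genes left out, the replicate number as a block, MuSC fits on the compared groups only, at least 5 CPM in both tissues for the tissue difference, and each library left out in turn. Thinning the libraries of a fit to their smallest total, and leaving out the Gm10800 family of repeat-like genes, were added after seeing the data. Family members share 25.2% to 77.5% of their 25-base words with other members. Replicate numbers recur across groups, and the labels say only that Maf-wt and MafΔTreg mice were littermates. Block fits held only libraries of the compared groups whose number occurs in both. Day 0 replicate 2 and day 1 PBS replicate 4 thus dropped out from day 0 to day 1. Day 1 PBS replicate 4 and day 3 PBS replicate 2 did so from day 1 to day 3, and muscle replicate 4 in Tregs. For liver, each library correlated best with the library of its own number (0.296, 0.200 and 0.125), so blocked values are given there. With 3 libraries per group such a match can arise by chance, and no other comparison checked showed it. Pairs are thus possible but not established. Other splits of the libraries into groups of the same sizes were fitted as well: all of them, or 100 drawn with seed 1.

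The procedure was tested on simulated data, in which 200 genes were changed by 2-fold or 4-fold in counts drawn with each comparison's spread. edgeR recovered 43% and 69% of these in Tregs (10964 genes), 54% and 84% from day 0 to day 1 (13029), 44% and 76% from day 0 to day 3 (13016), and 34% and 79% from day 1 to day 3 (13020). With rIL-17A it recovered 54% and 85% at day 1 (13014), 33% and 82% at day 3 (12984), and 19% and 64% for the difference between days (13008). For the deletion these were 61% and 95% in muscle (10524), 42% and 79% in liver (10789), and 18% and 88% for the difference between tissues (9156). Of the calls, 0.862% to 9.45% were false. Figures were drawn with matplotlib 3.10.9, and tables read with pandas 2.3.3 and numpy 2.4.6. Sex-linked marker genes were too few to test as a list, and no library was left out.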

Results

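The data are read counts from 34 mouse RNA-seq libraries in 11 groups. Regulatory T cells (Tregs) that express the transcription factor RORγ were sorted from the colon (3 libraries) and from muscle 3 days after an injection of cardiotoxin, a toxin that destroys muscle fibres (4 libraries). Muscle stem cells (MuSCs) were sorted in batches of 1000 cells from uninjured muscle (day 0) and at days 1 and 3 after cardiotoxin, from mice given recombinant interleukin-17A (rIL-17A) or saline (PBS), with 3 libraries in each of the 5 groups. Whole muscle was taken 7 days after cardiotoxin, and whole liver after 7 days on a choline-deficient, high-fat diet that causes fatty liver disease. Each tissue gave 3 libraries from MafΔTreg mice, in which Foxp3-driven Cre deletes the transcription factor gene Maf from Tregs, and 3 from Maf-wt littermates. Total counts per library ranged from 3974736 to 5317181 for day 0 MuSCs, 4785350 to 4972945 for day 1 PBS, 2170225 to 5107704 for day 1 rIL-17A, 733202 to 791937 for day 3 PBS and 4603717 to 5616432 for day 3 rIL-17A. Colon Tregs had 4735824 to 5066294 counts, muscle Tregs 2418975 to 3873293, Maf-wt muscle 1897672 to 2590359, MafΔTreg muscle 2295156 to 5003099, and the liver libraries 3415866 to 5245474. The labels do not say whether the replicates of a group are separate animals, so each p measures the spread between samples, which can be technical. Lower bounds on folds given below for genes with no count in a group cover counting error only.

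**Figure D1:**
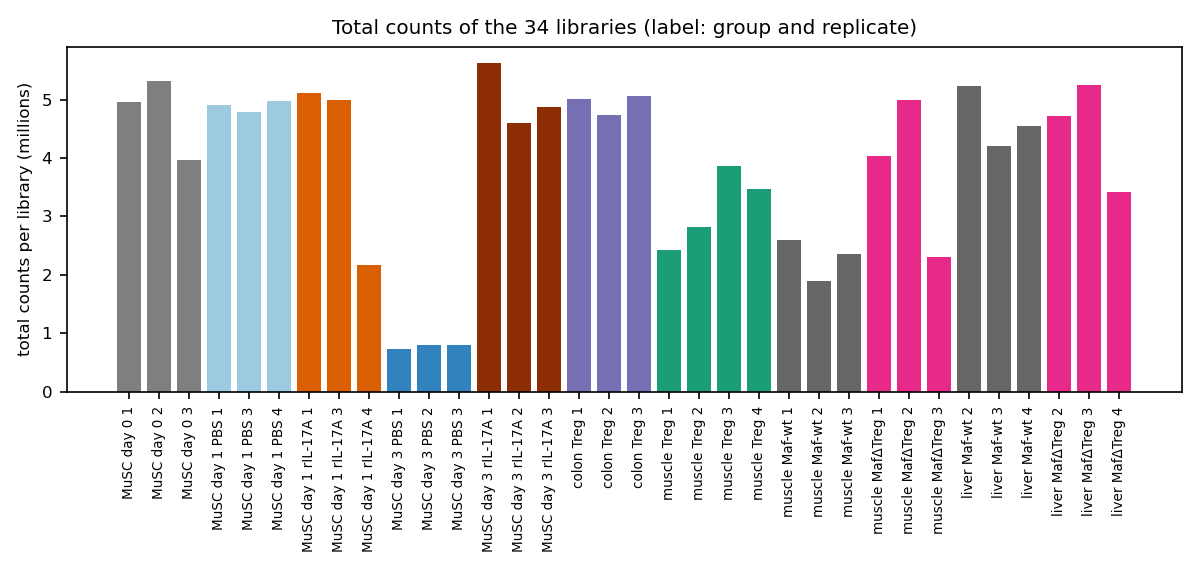
Total counts of each library (bars), coloured by group. The 3 day 3 PBS MuSC libraries hold 733202 to 791937 counts, below every other library.

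How RORγ+ Tregs of injured muscle differ from those of the colon was examined in 7 libraries. Muscle Tregs held less RNA of type 17 genes, Il10 and Lag3. Genes for passage through lymphoid tissue and interferon response genes were higher as lists with a preset correlation, but not with an estimated one (adjusted p = 0.0787 and 0.244), and 6 of 31 interferon genes were lower against 20 higher. Nrp1, a receptor common on Tregs of thymic origin, stood at 928 ± 49.8 CPM (counts scaled to the library total; mean ± SD, n = 4) in muscle and at 54.9 ± 22.2 CPM (n = 3) in the colon, a log2 change of 4.19 ± 0.22 (SE). Il10, which encodes an anti-inflammatory cytokine, stood at 111 ± 62.7 CPM in muscle and 3214 ± 293 CPM in the colon (log2 change -4.75 ± 0.31). Il17a was at 54.3 ± 18.9 CPM in colon Tregs and had no count in the 4 muscle libraries. It was at least 227-fold lower against a floor of 3 counts over the group. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, used for every adjusted p of a gene below unless another tool is named, called 2159 of 11362 genes, 1278 higher and 881 lower in muscle. In GRCm38 (mm10, GENCODE M21) Nrp1 (ENSMUSG00000025810) lies on chromosome 8 from 128358604 to 128503363, Il10 (ENSMUSG00000016529) on chromosome 1 from 131019845 to 131024974 and Il17a (ENSMUSG00000025929) on chromosome 1 from 20730905 to 20734496.

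Genes of the sorting gate were read next. Foxp3, the lineage factor of Tregs, was higher in muscle (540.2 ± 85.7 against 339 ± 34.6 CPM, log2 change 0.78 ± 0.13, adjusted p = 0.00106). Rorc, which encodes RORγ, fell from 226 ± 3.64 to 77.1 ± 27.9 CPM (-1.45 ± 0.24, adjusted p = 0.00105). Maf fell from 376 ± 71.1 to 163 ± 21.1 CPM (-1.09 ± 0.16, adjusted p = 0.000276) and Cd4 from 1376 ± 134 to 637 ± 63.0 CPM (-1.0 ± 0.12, adjusted p = 6.37e-05). Thy1 was at 292 ± 45.3 and 261 ± 17.6 CPM and was not called (adjusted p = 0.172). Il17ra, the shared receptor chain for IL-17A, was higher in muscle Tregs (275 ± 26.1 against 185 ± 25.8 CPM, log2 change 0.68 ± 0.14).

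Gene lists, each fixed before the values were seen, were tested with camera at a preset correlation, and all adjusted p of lists are Benjamini-Hochberg values over the lists of a comparison. Among them, lymphoid recirculation held 9 genes called higher and 1 lower of 14 (adjusted p = 2.76e-11; adjusted p = 0.0787 with an estimated correlation). S1pr1, the receptor that lets lymphocytes leave lymphoid organs, rose by 3.88 ± 0.21, S1pr4 by 2.45 ± 0.16, the homing receptor Sell by 4.61 ± 0.59 and the integrin chain Itgb1 by 5.46 ± 0.38 (log2). Interferon response genes were called higher in 20 and lower in 6 of 31 cases (adjusted p = 1.28e-05; adjusted p = 0.244 with an estimated correlation), with Ifit1 at 3.76 ± 0.31 and Rsad2 at 3.97 ± 0.44. The RORγ and type 17 programme had 8 of 16 genes lower and 1 higher (adjusted p = 1.73e-08; adjusted p = 0.0490 with an estimated correlation), among them Ccl20 (-7.68 ± 0.47), Il21 (-5.08 ± 0.56) and Il23r (-5.04 ± 0.59). Of 13 genes for gut residence and homing, 6 were lower and 3 higher (adjusted p = 0.000453; adjusted p = 0.0723 with an estimated correlation). The gut-homing receptor Ccr9 fell by 5.80 ± 0.39 on the log2 scale, Gpr34 changed by -5.37 ± 0.54 and Rgs1 by -2.18 ± 0.11. In the Treg core list, 10 of 24 genes were lower and 5 higher (adjusted p = 0.00681; adjusted p = 0.244 with an estimated correlation), with Lag3 (-6.24 ± 0.32) and Gzmb (-2.32 ± 0.12) down and Nrp1 up. Adjusted over the list alone, the counts differed only for interferon response (21 higher) and Treg core (6 higher) among these lists.

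Other lists moved both ways. The ST2 and GATA3 repair list, named after a Treg type of injured tissue, had 4 of 13 genes higher and 3 lower (5 and 3 adjusted over the list alone; adjusted p = 0.626), with a median log2 change of -0.09 and a mean of 0.71. Il1rl1, which encodes ST2, rose from 44.0 ± 27.9 to 525 ± 102 CPM (3.68 ± 0.39) and Pparg by 7.08 ± 0.93, while Irf4 fell by 1.20 ± 0.13. Chemokine receptors (adjusted p = 0.0734) included Ccr3, higher by 3.24 ± 0.38, and Ccr5 and Ccr1, which changed by -2.54 ± 0.16 and -2.35 ± 0.18. Of 24 T cell receptor and AP-1 genes, 7 were higher and 6 lower (8 and 7 adjusted over the list alone; adjusted p = 0.444, median -0.21, mean 0.13). Nr4a1 (1.57 ± 0.14) and Nr4a2 (3.85 ± 0.25) were up, and Klf6 (-1.83 ± 0.10) and Jun (-3.20 ± 0.21) down. The remaining lists of heat shock, cell cycle, glycolysis, oxidative phosphorylation, ribosome biogenesis, IL-17 ligands and receptors, and B cell markers gave adjusted p from 0.0729 to 0.618. The median of the IL-17 ligand and receptor list was 0.23 and its mean -1.33. Among the largest increases were St8sia6 (8.09 ± 0.71), Ifit3b (7.13 ± 0.65) and Popdc2 (6.59 ± 0.64), and Ccr10, absent from the colon libraries, was at least 48.9-fold higher (28.2-fold without muscle replicate 4). Cap2 had no count in muscle Tregs and was at least 64.6-fold lower, and Daw1 (-6.88 ± 0.66) and Marcks (-6.65 ± 0.87) also fell. The repeat-like Gm10800 family took 5.62% to 16.2% of counts in muscle Tregs and 4.02% to 4.59% in colon Tregs. Total counts also parted the libraries by tissue (2418975 to 3873293 in muscle, 4735824 to 5066294 in colon). The count of 2159 calls stayed within 1.5-fold of itself in thinned libraries and without the family. A share of library quality in these calls still cannot be told apart from tissue.

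**Figure D2:**
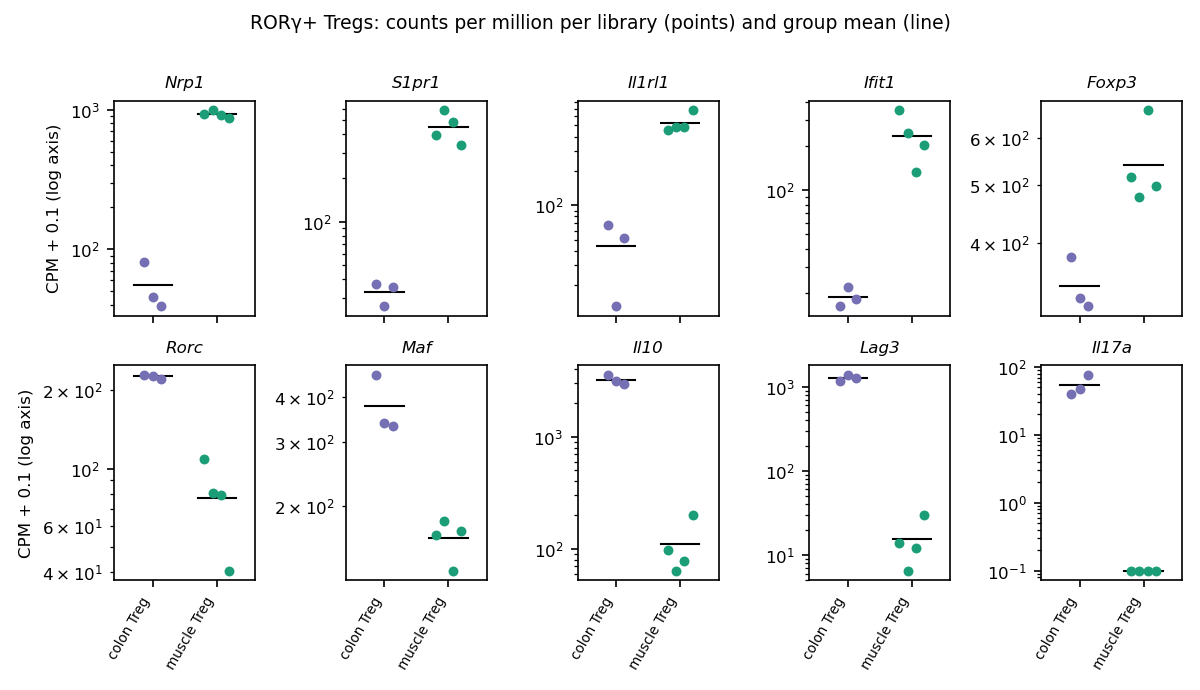
CPM plus 0.1 on a log axis for each RORγ+ Treg library (points) and the group mean (lines), 3 from colon and 4 from injured muscle. Nrp1, S1pr1, Il1rl1, Ifit1 and Foxp3 are higher in every muscle library, and Rorc, Maf, Il10, Lag3 and Il17a are lower.

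The course of MuSCs after injury was read from the PBS groups. One day after cardiotoxin, MuSCs had turned on replication genes, and their libraries held less RNA of immediate early genes. Of these, the 8 transcripts most often raised by tissue digestion had a mean log2 level of 7.99 to 8.51 at day 0, 6.90 to 7.24 at day 1 and 5.84 to 6.20 at day 3, so a share of handling stress in the fall is left open. Quiescence and interferon genes were lower as lists with a preset correlation, but not with an estimated one (adjusted p = 0.13 each). The helicase subunit Mcm2 rose from 5.25 ± 2.00 CPM at day 0 to 467 ± 65.8 CPM at day 1 (n = 3 each, log2 change 6.13 ± 0.19, adjusted p = 1.94e-15). Calcr, which encodes the calcitonin receptor that keeps MuSCs quiescent, fell from 201 ± 5.34 to 45.4 ± 1.59 CPM (-2.46 ± 0.18, adjusted p = 5.29e-10). Of 13434 genes tested, 3348 were called higher and 3700 lower at day 1. Mcm2 (ENSMUSG00000002870) lies on chromosome 6 from 88883474 to 88898780 and Calcr (ENSMUSG00000023964) on chromosome 6 from 3685680 to 3764714.

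All 35 cell cycle genes rose by day 1 (median log2 change 4.02, adjusted p = 9.39e-65; adjusted p = 0.0121 with an estimated correlation). Mcm5 rose by 4.21 ± 0.16 and Mcm3 by 3.69 ± 0.16, and Gmnn and Melk, without a count at day 0, were at least 199-fold and 179-fold higher. Immediate early genes fell in 20 of 23 cases and rose in 1 (adjusted p = 7.75e-10; adjusted p = 0.0195 with an estimated correlation), with Egr1 from 1121 ± 281 to 228 ± 41.5 CPM (-2.61 ± 0.19), Egr2 (-2.60 ± 0.16) and Atf3 (-2.02 ± 0.11). Of 26 quiescence and Notch genes, 18 fell and 0 rose (adjusted p = 2.17e-06; adjusted p = 0.13 with an estimated correlation; 18 adjusted over the list alone), among them the Notch target Heyl (-2.19 ± 0.20) and Notch3 (-1.15 ± 0.11). Interferon response genes fell in 20 of 28 cases and rose in 2 (adjusted p = 3.12e-06; adjusted p = 0.13 with an estimated correlation), with Gbp2 at -2.89 ± 0.21, Irgm1 at -2.64 ± 0.21 and Irf9 at -2.40 ± 0.16. Oxidative phosphorylation genes rose in 18 of 24 cases and fell in 1 (adjusted p = 0.000554; adjusted p = 0.458 with an estimated correlation), with Ndufs2 at 1.10 ± 0.11. Adjusted over the list alone, the counts were 21 lower for the immediate early and the interferon lists and 19 higher for oxidative phosphorylation. Il17ra, through which MuSCs sense IL-17A, fell from 560.2 ± 35.3 to 163 ± 33.4 CPM (-2.09 ± 0.13, adjusted p = 7.76e-11). Il17rc, its partner chain, was at 34.2 ± 2.79 and 36.7 ± 5.83 CPM and was not called (adjusted p = 0.379).

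Some genes of fibroblasts also rose at day 1, with a wide spread between libraries. The fibroblast marker list had 8 of 12 genes higher and 2 lower (adjusted p = 0.0171; adjusted p = 0.458 with an estimated correlation; 8 and 2 adjusted over the list alone). Dcn went from 3.50 ± 2.30 to 1582 ± 1058 CPM (8.45 ± 0.64), Col1a2 from 14.9 ± 1.56 to 791 ± 586 CPM and Fbln1 from 5.19 ± 0.745 to 103 ± 70.2 CPM, while Dpt fell from 280 ± 16.5 to 80.7 ± 22.1 CPM. Thbs4, a matrix protein of tendon, rose from 0.845 ± 0.900 to 6943 ± 4381 CPM, Prg4 from 0.260 ± 0.226 to 1278 ± 840 CPM and Il1rl1 from 0.991 ± 1.13 to 927 ± 641 CPM. Haemoglobin transcripts were at 29.4 ± 23.5 (Hba-a1) and 74.7 ± 61.2 CPM (Hbb-bs) at day 1 against 1.01 ± 1.57 and 4.01 ± 6.95 CPM. The 5 erythroid markers tested were each called higher but not as a list (adjusted p = 0.171), and limma voom called neither Hba-a1 (adjusted p = 0.160) nor Hbb-bs (adjusted p = 0.263), whose reads near-identical neighbours can share. Ribosome biogenesis (14 of 20 lower, adjusted p = 0.0337; Nop56 at -0.70 ± 0.09) and heat shock (9 of 14 lower, adjusted p = 0.0414) lost their calls with an estimated correlation (adjusted p = 0.458 for each) and when day 0 replicate 1 (adjusted p = 0.0979 and 0.0679) or day 1 PBS replicate 4 (0.113 and 0.0669) was left out. Heat shock was also lost without day 0 replicate 2 (0.109) and ribosome biogenesis without day 1 PBS replicate 3 (0.0570). The lists of commitment, differentiation, fibre, glycolysis, IL-17 and NF-κB target, matrix, stress and p53 genes gave adjusted p from 0.0670 to 0.985. Of these, the differentiation list had a median of -0.43 and a mean of 0.34, and the matrix list a median of -0.20 and a mean of 0.64. Genes that fell most included Il1rn, Hp and Ibsp, which had no count at day 1 and were at least 103-fold, 85.8-fold and 42.1-fold lower, and S100a2 (-4.75 ± 0.63). Day 0 replicate 2 sets much of the first 2 bounds: Il1rn was at 21.1 ± 28.6 CPM at day 0, and without that library the bounds were 22.6-fold and 46.4-fold.

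By day 3, MuSCs had entered the fusion programme of muscle. Myog, the factor that starts terminal differentiation, rose from 0.318 ± 0.389 CPM at day 0 to 1028 ± 246 CPM at day 3 (11.02 ± 0.75, adjusted p = 7.37e-11), and the fusion protein gene Mymk from 0.0839 ± 0.145 to 198 ± 41.2 CPM (10.60 ± 0.54, adjusted p = 7.96e-13). Mymx, its partner in fusion, had no count at day 0 and was at least 157-fold higher. At day 3, 3915 genes were called higher and 4244 lower than at day 0. Myog (ENSMUSG00000026459) lies on chromosome 1 from 134289989 to 134292548 and Mymk (ENSMUSG00000009214) on chromosome 2 from 27061636 to 27072179.

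Against day 0, 19 of 24 differentiation and fusion genes were higher and 4 lower (adjusted p = 2.65e-10; adjusted p = 0.0385 with an estimated correlation). Mature fibre genes were higher in 9 of 12 cases (adjusted p = 1.27e-05; adjusted p = 0.0888 with an estimated correlation), with Ttn, the giant sarcomere protein, at 5.85 ± 0.26. Cell cycle genes were higher in 35 of 35 cases (adjusted p = 5.59e-57; adjusted p = 0.0141 with an estimated correlation), with Cdk1 at 7.91 ± 0.31 and Ccna2 at 7.03 ± 0.27. Oxidative phosphorylation (22 of 24 higher, adjusted p = 7.38e-11) and glycolysis (13 of 20 higher and 5 lower, adjusted p = 2.96e-05) each gave adjusted p = 0.0888 with an estimated correlation. The enolase gene Eno1 rose by 3.47 ± 0.10. Among lists that fell, immediate early genes were lower in 21 of 23 cases (adjusted p = 4.59e-12; adjusted p = 0.0146 with an estimated correlation). Ribosome biogenesis genes were lower in 17 of 20 (adjusted p = 2.76e-08; adjusted p = 0.0385 with an estimated correlation). Each list had 1 gene higher, and Egr1 (-4.26 ± 0.22) and Nop56 (-1.71 ± 0.10) were among those lower. Quiescence genes were lower in 17 of 26 cases and higher in 3 (adjusted p = 1.91e-06; adjusted p = 0.0888 with an estimated correlation). Calcr fell to 8.30 ± 3.44 CPM (-5.01 ± 0.28), Chodl by 5.44 ± 0.30 and Sdc4 by 3.55 ± 0.12 on the log2 scale. IL-17 and NF-κB targets were lower in 13 of 25 cases (adjusted p = 0.000190; adjusted p = 0.164 with an estimated correlation), such as the chemokine gene Cxcl1 (-2.95 ± 0.16). Matrix genes were lower in 19 of 28 cases and higher in 6 (adjusted p = 0.000349; adjusted p = 0.254 with an estimated correlation). Interferon genes were lower in 20 of 28 cases and higher in 2 (adjusted p = 0.00379; adjusted p = 0.243 with an estimated correlation) and heat shock genes lower in 11 of 14 and higher in 2 (adjusted p = 0.0117; adjusted p = 0.248 with an estimated correlation). Adjusted over the list alone, the counts differed by 1 gene for differentiation (20 higher) and immediate early genes (22 lower) and not for the other lists named here. Commitment, stress, fibroblast, erythroid and p53 lists were not called (adjusted p from 0.0628 to 0.803), the last with a median of 0.25 and a test direction of down. Myod1, which commits cells to muscle, fell from 5170 ± 542 to 723 ± 90.1 CPM (-3.24 ± 0.14) and Il17ra to 57.6 ± 8.12 CPM (-3.69 ± 0.16). Digestion transcripts were highest at day 0, as given above, and a share of handling in the falls against day 0 was not tested. Pdzd2, with no count at day 3, was at least 74.1-fold lower, a bound set by the low depth of that group, and Melk and Gmnn, absent at day 0, were at least 415-fold and 255-fold higher.

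From day 1 to day 3, 2014 genes rose and 2264 fell. Differentiation genes rose in 20 of 24 cases (adjusted p = 1.54e-34; adjusted p = 0.00173 with an estimated correlation) and fibre genes in 9 of 12 (adjusted p = 2.38e-22; adjusted p = 0.00200 with an estimated correlation). Mymk rose by 8.52 ± 0.42, Myog by 7.62 ± 0.55, Ttn by 5.6 ± 0.25 and the acetylcholine receptor gene Chrna1 by 2.15 ± 0.12. IL-17 and NF-κB targets fell in 18 of 25 cases and rose in 1 (adjusted p = 3.20e-15; adjusted p = 0.0124 with an estimated correlation), with Cxcl1 going from 1049.7 ± 100 to 112 ± 13.0 CPM (-3.31 ± 0.16) and Cxcl2 changing by -4.75 ± 0.41. Matrix genes fell in 22 of 28 cases (adjusted p = 5.89e-14; adjusted p = 0.0432 with an estimated correlation), with Lox at -4.24 ± 0.37. Ribosome biogenesis genes fell in 18 of 20 (adjusted p = 2.25e-12; adjusted p = 0.0124 with an estimated correlation), with Nolc1 at -1.01 ± 0.10. Dcn fell from 1582 ± 1058 to 49.4 ± 50.6 CPM (-5.12 ± 0.56) with the fibroblast marker list (6 of 12 lower, 1 higher, adjusted p = 0.0171; adjusted p = 0.316 with an estimated correlation). The call of that list was lost without day 1 PBS replicate 3 (adjusted p = 0.0767). Oxidative phosphorylation rose in 23 of 24 cases (adjusted p = 7.29e-13; adjusted p = 0.0535 with an estimated correlation), and glycolysis in 13 of 20 with 1 lower (adjusted p = 3.12e-07; adjusted p = 0.0432 with an estimated correlation). Cell cycle genes rose in 24 of 35 with 4 lower (adjusted p = 2.25e-12; adjusted p = 0.0755 with an estimated correlation). Immediate early (17 of 23 lower, adjusted p = 8.21e-08; adjusted p = 0.0235 with an estimated correlation), quiescence (11 of 26 lower, 4 higher, adjusted p = 0.00486; adjusted p = 0.244 with an estimated correlation) and commitment genes (8 of 18 lower, 4 higher, adjusted p = 0.00941; adjusted p = 0.0598 with an estimated correlation) fell on balance. Adjusted over the list alone, counts moved by 3 genes at most, for IL-17 and NF-κB targets (21 lower). Heat shock, interferon, stress, p53 and erythroid lists were not called (adjusted p from 0.134 to 0.618). Dynap, Prkag3 and Gcnt1 had no count at day 1 and were at least 249-fold, 179-fold and 79.9-fold higher at day 3.

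What rIL-17A changes in MuSCs was tested on each day. At day 1, MuSC libraries of rIL-17A-treated mice held more RNA of heat shock, immediate early and IL-17 target genes and less of ribosome biogenesis genes. Matrix genes were higher in the same libraries (median 0.81), but so were fibroblast markers (median 1.11), and whether MuSCs are the source is left open. With the fibroblast marker level in the fit, the IL-17 target median went from 1.18 to 0.56, so its source is partly open too. The inducible chaperone gene Hspa1a stood at 718 ± 161 CPM (n = 3) against 36.5 ± 13.2 CPM (n = 3) with PBS, a log2 change of 4.34 ± 0.46 (adjusted p = 7.70e-06), and its near-identical copy Hspa1b, which can share its reads, rose by 4.17 ± 0.42. Hsph1, a co-chaperone gene without such a copy, went from 849 ± 118 to 3263 ± 429 CPM (1.99 ± 0.14, adjusted p = 1.11e-07). Cxcl1, a neutrophil chemokine gene induced by IL-17A, went from 1049.7 ± 100 to 2385 ± 427 CPM (1.24 ± 0.13, adjusted p = 1.04e-05). Of 13434 genes, 462 were called higher and 181 lower. Hspa1a (ENSMUSG00000091971) lies on chromosome 17 from 34969190 to 34972156, Hsph1 (ENSMUSG00000029657) on chromosome 5 from 149614287 to 149636376 and Cxcl1 (ENSMUSG00000029380) on chromosome 5 from 90891241 to 90893115.

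Heat shock genes rose in 11 of 14 cases (median 0.90, adjusted p = 1.24e-33; adjusted p = 0.000367 with an estimated correlation), also Dnajb1 by 3.00 ± 0.28 and Bag3 by 1.46 ± 0.12. Immediate early genes rose in 15 of 23 cases (median 0.81, adjusted p = 2.15e-31; adjusted p = 0.000346 with an estimated correlation), with Nr4a1 at 1.58 ± 0.17, Nr4a3 at 1.77 ± 0.22 and Atf3 at 1.40 ± 0.11. IL-17 and NF-κB targets rose in 14 of 25 cases (median 1.18, adjusted p = 7.63e-26; adjusted p = 0.00248 with an estimated correlation). The metalloreductase gene Steap4 went from 78.7 ± 10.5 to 278 ± 10.5 CPM (1.87 ± 0.21), the NF-κB regulator Nfkbiz from 141 ± 2.49 to 273 ± 14.3 CPM (1.00 ± 0.13) and the cytokine gene Il6 from 13.4 ± 5.41 to 97.8 ± 34.8 CPM (2.93 ± 0.39). Ribosome biogenesis genes fell in 11 of 20 cases (median -0.40, adjusted p = 1.01e-15; adjusted p = 0.00392 with an estimated correlation), with Rrp12 at -0.70 ± 0.11 and Nop2 at -0.57 ± 0.11. Adjusted over the list alone, the counts were 13 higher and 1 lower for heat shock, 19 and 22 higher for the immediate early and IL-17 lists, and 16 lower for ribosome biogenesis. Outside the lists, the transcription factor gene Ikzf4 rose from 2.81 ± 0.886 to 23.5 ± 2.08 CPM (3.10 ± 0.39). Genes that fell included Hmox1, which encodes the haem-degrading enzyme (2461 ± 319 to 964 ± 105 CPM, -1.30 ± 0.18, adjusted p = 0.000151), Sox8 (-1.21 ± 0.24) and Myod1 (4011 ± 711 to 2493 ± 330 CPM, -0.64 ± 0.13, adjusted p = 0.00461). The fusion and differentiation genes Mymk (0.469 ± 0.813 to 4.47 ± 2.05 CPM, 3.22 ± 0.63, adjusted p = 0.00442) and Myog (4.85 ± 6.60 to 27.5 ± 17.1 CPM, 2.48 ± 0.58, adjusted p = 0.0152) went the other way. Without day 1 rIL-17A replicate 1 neither was called (adjusted p = 0.0554 and 0.118), nor was Myog without day 1 PBS replicate 1 (0.0751), in the compared groups only (0.0744), with DESeq2 (0.0780) or with limma voom (0.0852), nor Mymk with the block (0.0679). Il17ra itself was at 171 ± 10.3 and 163 ± 33.4 CPM and was not called (adjusted p = 0.740).

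Matrix genes rose in 16 of 28 cases (21 adjusted over the list alone; median 0.81, adjusted p = 1.01e-15; adjusted p = 0.0475 with an estimated correlation), with Col6a1 at 0.80 ± 0.14, Fbn1 at 0.95 ± 0.16, Sparc at 0.69 ± 0.14 and Postn at 2.02 ± 0.40. The fibroblast markers moved with them: 3 of 12 were higher (10 adjusted over the list alone; median 1.11, adjusted p = 1.74e-06; adjusted p = 0.0726 with an estimated correlation), with Lum at 1.40 ± 0.37, Fbln1 at 1.06 ± 0.29 and Col3a1 at 0.92 ± 0.23. The mean log2 level of the fibroblast markers was 3.31, 5.0 and 4.39 in day 1 PBS replicates 1, 3 and 4, and 5.26 to 5.80 with rIL-17A. Endoplasmic reticulum stress genes were higher in 5 of 20 cases and lower in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.00495; adjusted p = 0.212 with an estimated correlation), with Herpud1 at 0.92 ± 0.10 and Hspa5 at 0.70 ± 0.09. Cell cycle genes (2 of 35 higher, median 0.34, adjusted p = 3.38e-05; adjusted p = 0.341 with an estimated correlation) lost their call without day 1 PBS replicate 1 (adjusted p = 0.0779). Quiescence, differentiation, glycolysis, interferon and fibre lists were called with adjusted p from 0.00857 to 0.0496, but at 0.332 to 0.348 with an estimated correlation, and each also lost its call without at least 1 of the 6 libraries (adjusted p from 0.0510 to 0.549). Oxidative phosphorylation, commitment, p53 and erythroid lists were not called (adjusted p from 0.135 to 0.586), and the p53 list had a median of -0.02 and a mean of 0.18. The count of 643 genes became 259 without day 1 PBS replicate 1, 392 without day 1 PBS replicate 4, 298 without day 1 rIL-17A replicate 1 and 252 without day 1 rIL-17A replicate 3. Of the 58 genes called under the rule for named genes, 17, 10, 14 and 16 lost their call without these libraries (adjusted p from 0.0508 to 0.784), and 5 each without day 1 PBS replicate 3 and day 1 rIL-17A replicate 4. Lum, Fbln1, Col3a1, Myog and Mymk were among them, Sox8 ended only in thinned libraries, and the other called genes in this and the paragraph before kept theirs.

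At day 3, few genes differed between rIL-17A and PBS. Bgn, a matrix proteoglycan gene (ENSMUSG00000031375, chromosome X from 73483602 to 73495933), stood at 298 ± 18.3 CPM against 161 ± 18.1 CPM (0.92 ± 0.15, adjusted p = 0.0219). The 4 genes called lower, outside the rule for named genes and picked after their values were seen, were the repeat-like predicted genes Gm10800 (-1.06 ± 0.15, adjusted p = 0.00995), Gm21738 (-1.06 ± 0.17), Gm10801 (-0.97 ± 0.15) and Gm10718 (-1.42 ± 0.25), which share 42.95% to 77.5% of their 25-base words with other members of their family, so reads from those parts fit more than 1 gene. The 5 calls compare with 965 genes at an unadjusted p below 0.05, 13 calls with DESeq2 (9 higher), 3 with limma voom and 270 (261 higher, 9 lower) without the filter on low counts. No gene was called without day 3 PBS replicate 1, 2 or 3 or day 3 rIL-17A replicate 3 (Bgn adjusted p = 0.157, 0.0730, 0.0978 and 0.122), and 41 were without day 3 rIL-17A replicate 1. Tmem87b (-0.78 ± 0.19) and Iqsec1 (-0.74 ± 0.18) came next among lower genes and did not pass (adjusted p = 0.4 each). The matrix list was called higher with 1 of 28 genes passing (2 adjusted over the list alone; median 0.41, adjusted p = 2.36e-08; adjusted p = 0.649 with an estimated correlation), where Lox was at 88.7 ± 4.59 and 33.9 ± 6.12 CPM (adjusted p = 0.408). The fibroblast markers (median 0.81, 0 called, adjusted p = 0.00212) and ribosome biogenesis (median 0.08, 0 called and 2 adjusted over the list alone, adjusted p = 0.0394) also gave adjusted p = 0.649 with an estimated correlation. The first was lost without day 3 PBS replicate 3 (adjusted p = 0.155), the second without day 3 PBS replicate 2 (0.101) or day 3 rIL-17A replicate 1 (0.0716). Heat shock (median 0.10), immediate early (0.07) and IL-17 target genes (0.13) held 0 called genes, with list adjusted p of 0.0851, 0.859 and 0.373. The other lists were not called either (adjusted p from 0.0851 to 0.859); among them the interferon list had a median of 0.01 and a mean of -0.02, and the cell cycle list -0.01 and 0.02. Il17ra was at 66.7 ± 6.22 and 57.6 ± 8.12 CPM (adjusted p = 0.790).

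A direct test of the difference between the effects of rIL-17A at day 3 and day 1 called 76 genes, 16 with a higher and 60 with a lower log2 effect at day 3. Without the filter on low counts these were 302 and 102, with DESeq2 59 and 166, and with limma voom 76 and 144. The effect was smaller at day 3 for Hsph1 (difference -1.82 ± 0.20, adjusted p = 0.000168), Dnajb1 (-2.97 ± 0.39), Atf3 (-1.41 ± 0.18), Nr4a1 (-1.81 ± 0.29), Hspa1a (-4.20 ± 0.73) and Cxcl1 (-1.21 ± 0.21). Cxcl1 was at 112 ± 17.9 CPM with rIL-17A and 112 ± 13.0 CPM with PBS at day 3, and Hspa1a at 49.0 ± 8.83 and 45.8 ± 16.1 CPM. Hmox1 differed the other way (1.59 ± 0.26, adjusted p = 0.00531). Lists that differed were heat shock (6 of 14 lower, 7 adjusted over the list alone, adjusted p = 4.18e-22; adjusted p = 0.00339 with an estimated correlation) and ribosome biogenesis (2 of 20 higher, 15 adjusted over the list alone, adjusted p = 2.58e-16; adjusted p = 0.00410 with an estimated correlation). So did immediate early genes (5 of 23 lower, 10 adjusted over the list alone, adjusted p = 1.94e-15; adjusted p = 0.00339 with an estimated correlation) and IL-17 targets (3 of 25 lower, 8 adjusted over the list alone, adjusted p = 6.24e-10; adjusted p = 0.0424 with an estimated correlation). Cell cycle, differentiation, matrix, stress, fibre, glycolysis and fibroblast lists were lower with the preset correlation (adjusted p from 0.000203 to 0.0449) but gave 0.212 to 0.401 with an estimated correlation. The remaining lists were not called (adjusted p from 0.0712 to 0.901). Leaving out 1 library left between 14 (without day 3 PBS replicate 2) and 110 calls. The count fell to 22 without day 3 PBS replicate 1, 36 and 42 without day 1 PBS replicates 1 and 4, 37, 34 and 37 without day 1 rIL-17A replicates 1, 3 and 4, and 29 and 27 without day 3 rIL-17A replicates 2 and 3. Hspa1a was not called without day 3 PBS replicate 1 (adjusted p = 0.0757) nor Cxcl1 without day 3 PBS replicate 2 (0.0742).

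**Figure D3:**
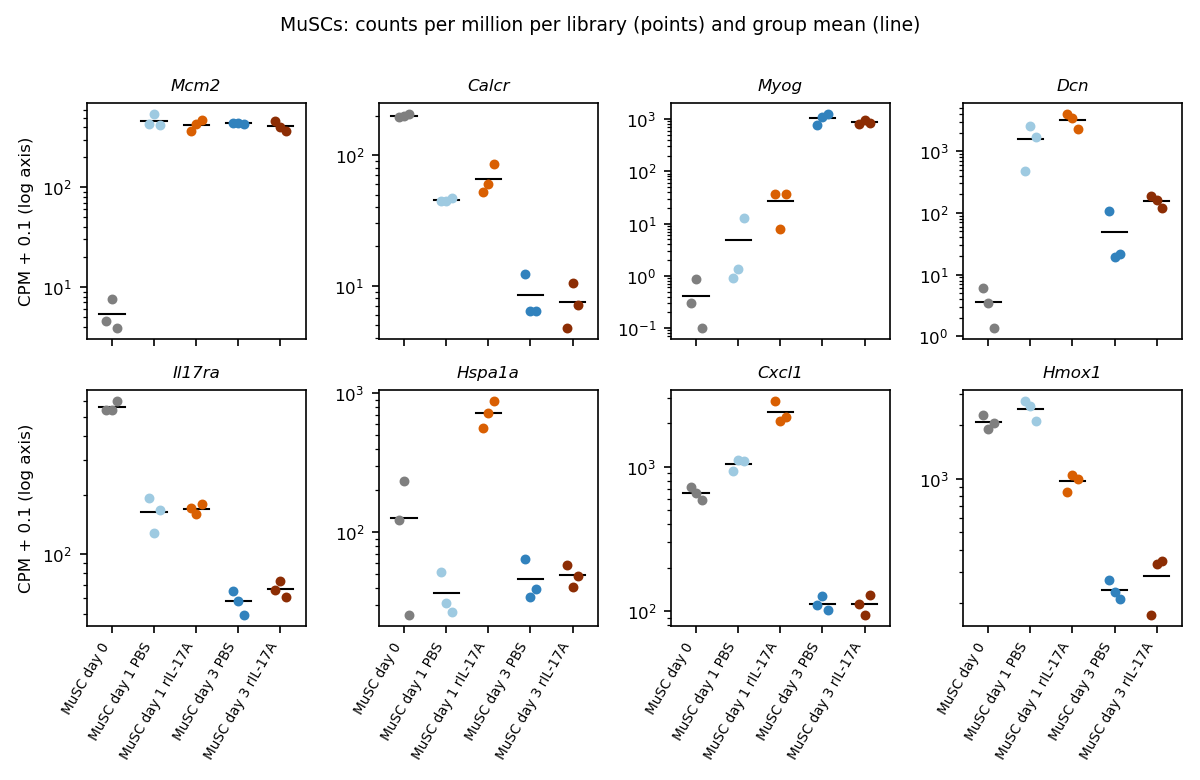
CPM plus 0.1 on a log axis for each MuSC library (points) and the group mean (lines), 3 libraries per group. Hspa1a and Cxcl1 are higher and Hmox1 lower with rIL-17A at day 1 in every library, and the rIL-17A and PBS libraries overlap at day 3.

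Whether loss of Maf in Tregs changes regenerating muscle was tested in 6 whole muscle libraries. Maf was at 29.2 ± 7.90 CPM (n = 3) in MafΔTreg and 43.5 ± 6.75 CPM (n = 3) in Maf-wt muscle (log2 change -0.53 ± 0.22, adjusted p = 0.269). Since the gene is deleted in Tregs only, its level in whole tissue checks the labels weakly. MafΔTreg muscle held more RNA of Gsn and C3 and less of Tbx1 and Phlda3. The actin-severing protein gene Gsn rose from 172 ± 20.9 to 471 ± 49.3 CPM (1.5 ± 0.16, adjusted p = 8.33e-05) and complement C3 from 16.1 ± 3.68 to 59.0 ± 20.5 CPM (1.93 ± 0.26, adjusted p = 0.000642). Tbx1, a transcription factor gene, fell from 34.2 ± 2.52 to 6.96 ± 4.11 CPM (-2.23 ± 0.31, adjusted p = 0.000944). Of 10756 genes, 30 were called higher and 97 lower. Gsn (ENSMUSG00000026879) lies on chromosome 2 from 35256380 to 35307892 and Tbx1 (ENSMUSG00000009097) on chromosome 16 from 18580979 to 18590671.

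Among genes that rose were also the matrix protein gene Fmod (1.41 ± 0.20, adjusted p = 0.00163), Myoc (2.33 ± 0.36, adjusted p = 0.00285) and the chemokine gene Ccl6 (1.76 ± 0.30, adjusted p = 0.00526). Genes that fell included Phlda3, a p53 target (212 ± 28.4 to 81.0 ± 17 CPM, -1.34 ± 0.17, adjusted p = 0.000380), Cited4 (-2.50 ± 0.40), Cox11 (-2.41 ± 0.40) and the potassium channel gene Kcna7 (-2.03 ± 0.33). Adipocyte genes were higher as a list (1 of 6 called, 4 adjusted over the list alone, median 0.65, adjusted p = 5.37e-06; adjusted p = 0.135 with an estimated correlation), with Cfd at 55.0 ± 20.5 against 19.2 ± 1.85 CPM (1.58 ± 0.26). Fibroblast markers were higher (2 of 13 called, 4 adjusted over the list alone, median 0.24, adjusted p = 2.15e-05; adjusted p = 0.318 with an estimated correlation), with Pi16 at 1.85 ± 0.36 and Dcn at 0.87 ± 0.19. Erythroid markers (1 of 5 called, 4 adjusted over the list alone, median 1.17, adjusted p = 7.22e-05; adjusted p = 0.405 with an estimated correlation) included Hbb-bs at 79.5 ± 30.9 against 32.5 ± 14.1 CPM. Macrophage markers (0 of 15 called, 4 higher and 1 lower adjusted over the list alone, median 0.39, adjusted p = 0.000138; adjusted p = 0.417 with an estimated correlation) were called as a list. Of 11 IL-17 and NF-κB targets, Steap4 was higher (1.16 ± 0.24; median 0.31, adjusted p = 0.0293; adjusted p = 0.318 with an estimated correlation; 1 adjusted over the list alone). This list's call was lost without Maf-wt replicate 2 (adjusted p = 0.0602) or 3 (0.132) and without MafΔTreg replicate 1 (0.182) or 2 (0.112). Oxidative phosphorylation (median 0.18, adjusted p = 0.000515), lipid-associated macrophage (0.20, adjusted p = 0.00705), glycolysis (0.14, adjusted p = 0.00965) and heat shock genes (0.18, adjusted p = 0.0293), with 0 members called, gave adjusted p from 0.318 to 0.640 with an estimated correlation. Each lost its call without Maf-wt replicate 1 (adjusted p = 0.119, 0.625 and 0.0838 for oxidative phosphorylation, glycolysis and heat shock), or, for the macrophage list, without Maf-wt replicate 3 (0.0692) or MafΔTreg replicate 1 (0.0900). Heat shock was lost without Maf-wt replicate 2 (0.0732) and MafΔTreg replicate 1 (0.267) as well. The other lists, among them quiescence, differentiation, fibre, matrix, interferon, p53 and circadian genes, were not called (adjusted p from 0.104 to 0.913). Median and mean differed in sign for matrix (0.04 and -0.07), p53 (0.11 and -0.05), commitment (0.01 and -0.05) and immediate early genes (0.09 and -0.01).

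Mitochondrial genes took 7.28% to 7.62% of counts in MafΔTreg and 5.32% to 5.82% in Maf-wt muscle. Lars2 was at 1036 to 1262 CPM against 1910 to 3995 CPM, and Maf-wt replicate 1 detected 24646 genes, the most of the 6 libraries. Thinned to the same total, Maf-wt libraries detected 15127 to 18156 genes and MafΔTreg libraries 14623 to 15253, ranges that overlap. Mitochondrial share and Lars2 thus parted the libraries by genotype. A share of library quality in the 127 calls therefore cannot be told apart from the deletion. The 127 calls became 75, 40 and 401 without Maf-wt replicates 1, 2 and 3, and 18 and 68 without MafΔTreg replicates 2 and 3. Without MafΔTreg replicate 2, 16 of the 25 named genes called lost their call (adjusted p from 0.0573 to 0.249), Cfd, Dcn, Steap4, Hbb-bs, Kcna7 and Cox11 among them. Without Maf-wt replicates 1 and 2, 7 and 9 named genes did (0.0510 to 0.339), with Dcn and Hbb-bs in both and Pi16 and Steap4 in the latter, and without MafΔTreg replicate 3, 4 did (0.0604 to 0.146). Gsn, C3, Fmod, Myoc, Ccl6, Tbx1 and Phlda3 kept their calls under every alternative, while DESeq2 did not call Cited4 (adjusted p = 0.160) or Hbb-bs (adjusted p = 0.210).

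Whether the same deletion changes fatty liver was tested in 6 liver libraries. Maf was at 5.34 ± 1.24 CPM in MafΔTreg and 10.3 ± 2.77 CPM in Maf-wt liver (n = 3 each, -0.99 ± 0.33, adjusted p = 0.999). Adipoq, which encodes the fat-cell hormone adiponectin, was at 18.8 ± 7.56 CPM in MafΔTreg and 0.153 ± 0.132 CPM in Maf-wt liver (6.71 ± 0.61, adjusted p = 0.00906). Cfd was at 114 ± 51.3 against 1.25 ± 1.96 CPM (6.44 ± 0.66, adjusted p = 0.0140) and Fabp4, a fatty acid carrier of adipocytes, at 40.9 ± 18.6 against 5.02 ± 1.44 CPM (2.96 ± 0.34, adjusted p = 0.0242). These 3 were the only genes called of 11038, with 0 lower; 343 genes had an unadjusted p below 0.05, DESeq2 called 20 (18 higher, 2 lower) and limma voom 2. Without the filter on low counts, 111 were called (82 higher, 29 lower). Replicate numbers may pair the liver samples, but the match of their correlations can arise by chance and the labels do not state pairs. With the number as a block, 12 genes were called higher and 0 lower. Adipoq (6.70 ± 0.51, adjusted p = 0.000475), Cfd (6.44 ± 0.54) and Fabp4 (2.91 ± 0.23) were among them. So were Ucp1, the uncoupling protein of brown fat (60 ± 40.0 against 0.891 ± 1.15 CPM, 6.03 ± 0.37 with the block, adjusted p = 0.000119) and Cidea (5.57 ± 0.58). Cox8b (6.23 ± 0.80), Slc36a2 (7.87 ± 0.99), Retn (7.75 ± 1.00), Atp1a2 (3.94 ± 0.53), Gsn (1.70 ± 0.18), Ifi27l2a (1.40 ± 0.18) and Slc25a25 (1.51 ± 0.22) complete the 12. These 9 beside Adipoq, Cfd and Fabp4 lie outside the rule and were picked after their values were seen. Adipoq (ENSMUSG00000022878) lies on chromosome 16 from 23146536 to 23158028, Cfd (ENSMUSG00000061780) on chromosome 10 from 79890853 to 79892655 and Fabp4 (ENSMUSG00000062515) on chromosome 3 from 10204088 to 10208576.

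No member of a tested list passed in liver, yet several lists were called with the preset correlation only. Interferon (32 genes, median 0.30, adjusted p = 2.51e-06; Mx2 at 0.97 ± 0.25 and Usp18 at 0.74 ± 0.20, not called), matrix (21 genes, median 0.64, adjusted p = 2.51e-06; Tnc at 1.82 ± 0.62 and Col1a1 at 0.99 ± 0.41, not called) and immediate early genes (15 genes, median 0.43, adjusted p = 1.88e-05) were higher, each at 0.547 with an estimated correlation. Acute phase genes were lower (22 genes, median -0.27, adjusted p = 0.000226; adjusted p = 0.597 with an estimated correlation), with the serum amyloid genes Saa1 (-1.15 ± 0.45) and Saa2 (-1.43 ± 0.57), near-identical copies, not called. The matrix and acute phase calls were lost without MafΔTreg replicate 3 (adjusted p = 0.0574 and 0.175). Fatty acid oxidation genes (21 genes, 1 called adjusted over the list alone, median 0.13, adjusted p = 0.00455; adjusted p = 0.547 with an estimated correlation) included Pdk4 at 2.78 ± 0.59 (adjusted p = 0.512). The call was lost without Maf-wt replicate 4 (adjusted p = 0.149) or MafΔTreg replicate 2 (0.316). Endothelial markers (median 0.28, adjusted p = 0.0183), lipid-associated macrophages (0.44, adjusted p = 0.0227) and cholesterol synthesis (-0.15, adjusted p = 0.0295) gave adjusted p from 0.547 to 0.879 with an estimated correlation, and each was lost without at least 3 of the 6 libraries. With the block, the bile acid list was called lower (median -0.16, adjusted p = 0.0301) and without it not (-0.13, adjusted p = 0.0633). Hepatocyte identity, lipogenesis, xenobiotic, circadian, stellate cell, Kupffer cell and the other lists were not called (adjusted p from 0.113 to 0.827). Median and mean differed in sign for glycolysis (-0.03 and 0.18) and hepatocyte identity (-0.04 and 0.05), and the IL-17 and NF-κB list had a median of -0.10 and a test direction of up. The adipocyte list was not tied to liver. Among genes lower in MafΔTreg liver none passed; the smallest p belonged to Aqp8 (-1.02 ± 0.19, adjusted p = 0.313) and Fn3k (-1.14 ± 0.23, adjusted p = 0.385). Il17ra was at 41.3 ± 1.49 and 35.3 ± 5.90 CPM (adjusted p = 0.999). No gene was called without Maf-wt replicate 3 or MafΔTreg replicate 4, 1 was without Maf-wt replicate 4 and 7 without MafΔTreg replicate 2. Adipoq reached adjusted p = 0.1175, 0.0706 and 0.0524 without Maf-wt replicate 3, MafΔTreg replicate 4 and Maf-wt replicate 4, Cfd 0.137 and 0.0706 without the first and second of these. Fabp4 lost its call without 5 of the 6 libraries (0.0720 to 0.188).

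The effects of the deletion in liver and muscle were then compared. A direct test called 10 of 9254 genes, 8 with a higher log2 effect in liver and 2 with a lower one; with the replicate block 22 were higher and 6 lower. Cox8b (6.12 ± 0.70, adjusted p = 0.000624), Atp1a2 (4.17 ± 0.51), Fabp4 (2.65 ± 0.34), Adipoq (5.86 ± 0.87) and Cfd (4.85 ± 0.72) had the higher effect in liver. Prg4 (-1.82 ± 0.32) and C3 (-1.93 ± 0.34, adjusted p = 0.0244) had the lower one; C3, made in hepatocytes, was at 5163 ± 246 and 4984 ± 1156 CPM in MafΔTreg and Maf-wt liver. Lists of interferon (0.37), matrix (0.54), immediate early (0.66) and oxidative phosphorylation genes (-0.23) differed with adjusted p from 0.00192 to 0.0132, but 0.798 with an estimated correlation, and each lost its call without at least 2 libraries (0.0590 to 0.491). The other lists were not called (0.122 to 0.973), and median and mean differed in sign for heat shock (-0.04 and 0.01), glycolysis (-0.16 and 0.01) and p53 genes (-0.08 and 0.11). With the block, the endoplasmic reticulum stress list was called lower (adjusted p = 0.0261; 0.122 without it). The count was 4 and 6 without muscle Maf-wt replicates 1 and 2, 5 without muscle MafΔTreg replicate 2 or 3, 6 without liver Maf-wt replicate 2 or liver MafΔTreg replicate 3, and 21 without liver MafΔTreg replicate 2. Adipoq was not called without muscle Maf-wt replicate 1 (adjusted p = 0.0544). Prg4 and C3 lost their calls when any of 7 and of 8 of the 12 libraries was left out (0.0510 to 0.146), while Cox8b, Atp1a2, Fabp4 and Cfd kept theirs. Across the 9254 genes, which are not independent replicates, the log2 changes in liver and muscle had r = 0.031 and rho = 0.0021. Of 22 genes called higher in muscle and 3 in liver, Cfd was shared, against 0.0071 expected for independent lists; 71 and 0 were called lower. With the liver replicate number as a block, 9 of the 9254 genes were called higher in liver, and Cfd and Gsn were shared, against 0.0214 expected. Leaving out 1 library gave r from -0.000573 (without liver MafΔTreg replicate 4) to 0.0523 (without liver MafΔTreg replicate 3), with 0.0467 and 0.0152 without muscle Maf-wt replicates 1 and 2 and 0.0150 without liver Maf-wt replicate 2.

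Genes higher with rIL-17A in the MuSC libraries at day 1 or day 3 were followed in whole muscle. The series treats IL-17A and RORγ+ Tregs as arms of a common question. Of 462 such genes, 381 were tested in whole muscle, with a median log2 change of 0.083 in MafΔTreg against Maf-wt. Ccn5, Dhrs3, Myoc, Phactr2, Prg4, Rian, Serpina3n, Steap4 and Ugdh were called, 7 of them higher and 2 lower. As a set they were higher with the preset correlation (adjusted p = 0.0106), and with an estimated correlation the unadjusted value was 0.310. That call was lost without Maf-wt replicate 2 (adjusted p = 0.0936) or 3 (0.0719) and without MafΔTreg replicate 1 (0.236). The 9 fibroblast markers that are not collagens were higher with rIL-17A at day 1 (median 1.10). The fibroblast list was also higher in MafΔTreg muscle, with the preset correlation only. A share of fibroblast RNA in both thus cannot be told apart from a response to IL-17A. Of 185 genes lowered by rIL-17A, 169 were tested, with a median of 0.038 (adjusted p = 0.133). Among them Hmox1 and the repeat-like Gm10800, Gm10801 and Gm21738 were called, 1 higher and 3 lower.

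**Figure D4:**
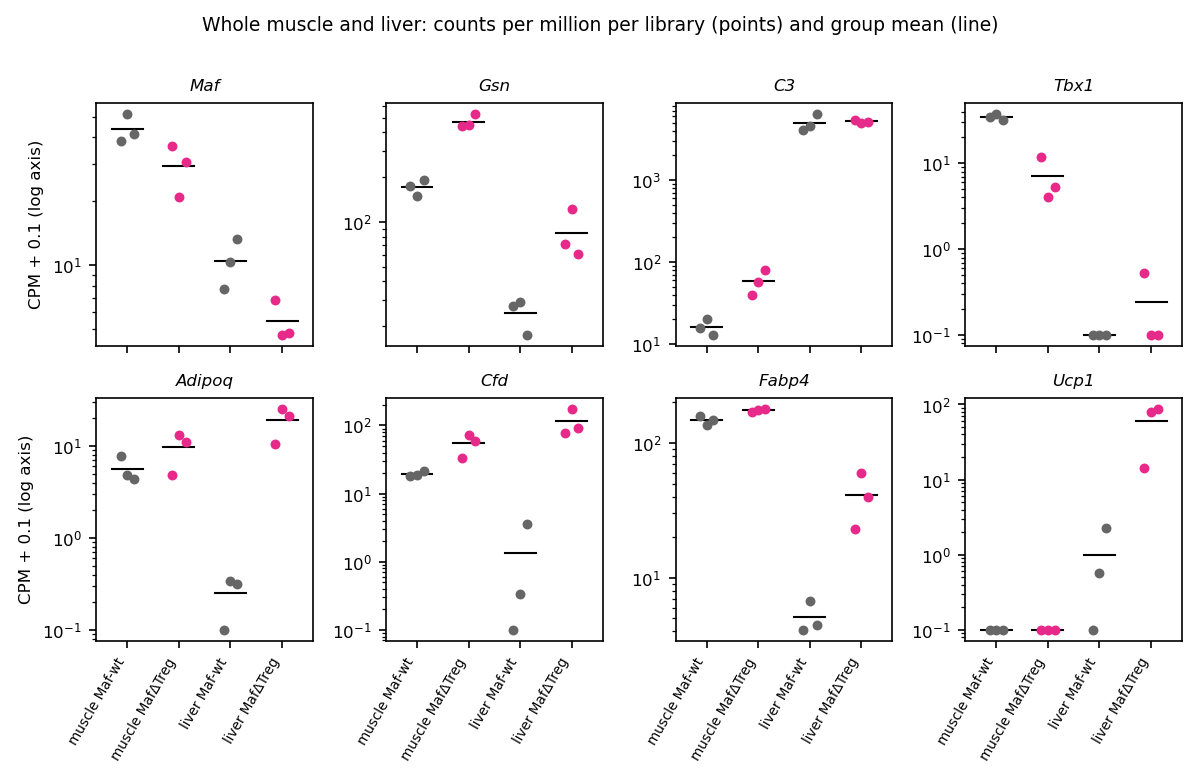
CPM plus 0.1 on a log axis for each whole muscle and liver library (points) and the group mean (lines), 3 libraries per group. Gsn and C3 are higher and Tbx1 lower in every MafΔTreg muscle library, and Adipoq, Cfd, Fabp4 and Ucp1 are higher in every MafΔTreg liver library than in any Maf-wt liver library.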

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

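Of the tests below, those of carried fibroblasts, of digestion stress, of carried adipose tissue and of lipid synthesis were chosen only after the result was seen.

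The first pattern is the low number of genes that differed with rIL-17A at day 3, 5 against 643 at day 1. Low depth of the day 3 PBS libraries is argued against as the whole reason: with the day 1 PBS libraries thinned to those totals, 326 genes were still called at day 1 (315 to 351 over 10 seeds). A smaller response at day 3 is what remains open: the 643 genes changed at day 3 by a median of 0.036 in their day 1 direction, against 0.83 at day 1, a ratio of 0.0434. These genes were picked by their day 1 test, which by itself raises their day 1 median and lowers the ratio. At day 3, 55.4% of them moved in that direction, with quartiles of -0.15 and 0.29, so a smaller response may explain the count, as a hypothesis. Why the response would be smaller was not tested.

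The second pattern, the set of genes higher with rIL-17A at day 1, has no tested explanation that the tables argue against for all of its genes. Fibroblasts carried into the sort may add to it, since the 9 fibroblast markers that are not collagens had a median log2 change of 1.10 against 0.81 for the matrix list, with Dcn at 1582 CPM on average at day 1 with PBS, and the labels used here do not give the gate of the sort. With the fibroblast level as a covariate, matrix genes kept 0.441 of their median (0.36) and 0 of 28 were called, of 95 genes in all. A direct effect on matrix genes cannot be told apart from carried cells, since the level itself differs between the groups. IL-17 targets fell as well, from a median of 1.18 to 0.56, so a share of carried cells is open for them too. Heat shock (0.83, and 0.90 without the covariate) and immediate early genes (0.85, and 0.81 without it) stayed about as high. In this fit the heat shock and immediate early lists did not depend on the marker level. Since that level differs between the groups, the fit cannot show which cells hold these transcripts. Ribosome genes (-0.34, and -0.40 without it) kept their direction. More stress during tissue digestion cannot be told apart either: the 8 transcripts most often raised by digestion had a median of 0.689 (0.18 to 1.21, 5 called) and a level of 7.67 to 7.88 with rIL-17A, 6.90 to 7.24 with PBS and 7.99 to 8.51 at day 0, but all belong to the immediate early list already seen higher, for which its rule was tightened after the value was seen. Heat shock genes had a level of 9.34 to 9.56 with rIL-17A, 7.81 to 8.16 with PBS and 8.26 to 8.95 at day 0. Day 0 libraries thus had the highest level of digestion transcripts but not of heat shock genes. A response of MuSCs to rIL-17A, which the design names, stays open beside these explanations.

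The third pattern is the higher level of Adipoq, Cfd and Fabp4, transcripts of adipocytes, in MafΔTreg liver. The tables argue against none of its explanations. Adipose tissue carried along with the liver pieces is undecided: all 4 brown fat genes tested were higher in every MafΔTreg library than in any Maf-wt library, with Ucp1 at 13.97 to 86.4 against 0 to 2.20 CPM, Cidea at 5.50 to 26.9 against 0 to 1.10, Cox8b at 4.66 to 11.7 against 0 to 0.191 and Slc36a2 at 3.18 to 10.9 against 0 CPM, but all 4 are among the genes called with the replicate block, so their level restates the pattern, and this rule too was tightened after the value was seen. More lipid synthesis in hepatocytes is undecided too: the lipogenesis list had a median of 0.314, above the bound of 0.3 first set, but only 10 of its 16 genes were higher (-0.77 to 0.60) with 0 called, and the rule was tightened after the value was seen to ask for all of them. Why carried tissue would follow genotype in all 3 libraries was not tested, and an effect of the deletion on fat around or in the liver stays open.

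Muscle Treg replicate 4 lay apart from the other 3 of its group in some genes. It had Sell at 147 CPM (others 78.1 to 83.4), Il1rl1 at 676 (455 to 489) and Gzmb at 715 (539 to 562). Replicate 2 had Il21 at 1.42 CPM (0.258 to 0.413), Daw1 at 1.07 (0) and Marcks at 0.356 (0), but these are 4, 3 and 1 counts against 1, 0 and 0 in each other library, too few to set it apart. Together these are 6 of 53 values tested, and chance alone sets apart about 1 in 20 groups.

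The effect of rIL-17A differed between day 3 and day 1, by a direct test, in 76 genes. The log2 difference was below zero for Hsph1 (-1.82), Dnajb1 (-2.97), Hspa1a (-4.20), Hspb1 (-2.32), Nr4a1 (-1.81), Atf3 (-1.41), Cxcl1 (-1.21), Mymk (-3.56), Arhgef17 (-2.10), Palmd (-2.53), Mmp13 (-11.04) and Traf3ip2 (-1.89). It was above zero for Hmox1 (1.59), Nolc1 (0.64), Myod1 (0.81), Nop14 (0.83), Ftsj3 (0.83), Ncl (0.78), Eif4a1 (0.79), L3mbtl2 (1.03), Rrp15 (0.86), Nifk (0.80) and Eif5b (0.83). Mmp13 was at 0.209 ± 0.362 CPM with PBS and 12.8 ± 12.4 CPM with rIL-17A at day 1, and at 17.3 ± 24.7 and 0.415 ± 0.720 CPM at day 3, so its value is a fitted one beside groups near 0 and no measure of size. It was not called without day 3 PBS replicate 2 (-8.60, adjusted p = 0.422), nor without 6 other single libraries. List medians that differed were those of immediate early (-0.61), heat shock (-0.84), cell cycle (-0.31), glycolysis (-0.13), differentiation (-0.26), fibre (-0.55), ribosome biogenesis (0.51), IL-17 target (-0.64), matrix (-0.47), stress (-0.17) and fibroblast genes (-0.40). With an estimated correlation only the immediate early, heat shock, ribosome biogenesis and IL-17 target lists held, and the other 7 gave adjusted p from 0.212 to 0.401. Of the 23 genes, 17 were not called without day 3 PBS replicate 2 and 11 without day 3 PBS replicate 1, while Hsph1, Dnajb1, Nr4a1, Atf3 and Hmox1 were called with any 1 library left out.

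The effect of the deletion differed between liver and muscle in 10 genes by a direct test. The log2 difference, liver minus muscle, was 6.12 for Cox8b, 5.56 for Cidea, 5.86 for Adipoq, 4.85 for Cfd, 4.17 for Atp1a2, 2.65 for Fabp4, 2.63 for Svep1, -1.82 for Prg4 and -1.93 for C3. Lists that differed had medians of 0.66 (immediate early), 0.37 (interferon), 0.54 (matrix) and -0.23 (oxidative phosphorylation). That held with the preset correlation only: each of the 4 gave adjusted p = 0.798 with an estimated correlation and lost its call in at least 2 of the fits that leave out a single library.

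Other splits of the same libraries into groups of the same sizes were fitted for each count of genes. For Tregs, 1 of 35 splits, the real one, gave as many (2159, highest other 0). That share, 0.0286, is the smallest that 35 splits can give, and it argues against chance. With 10 splits, which are too few to tell, the real split alone gave as many for day 1 against day 0 (7048), day 3 against day 0 (8159), day 3 against day 1 (4278), rIL-17A at day 1 (643), muscle (127) and liver (3), with a highest other of 0 in each, and 1 of 10 as large. For rIL-17A at day 3, 2 of 10 splits gave as many: the real one (5) and 1 with 77 genes, which sets day 3 rIL-17A replicate 1 and day 3 PBS replicates 2 and 3 against the rest and points to a structure of the samples. With liver blocked by number, 4 of the 10 splits part all 3 pairs, and the real one called 12 against a highest other of 0. For the difference between days, 3 of 100 splits gave as many (real 76, highest other 122), so other splits called more genes and chance is not excluded. For that between tissues, 3 of 100 did without the block (real 10, highest other 14), but among the 32 splits that part all 6 same-numbered pairs, with the block, 2 did (real 28, highest other 58), so chance is not excluded there. In all of these, the highest other split exchanges the labels of a whole contrast and so tests the sum of the effects, and the next highest other splits called 78, 12 and, with the block, 14 genes.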

How the results depend on the processing

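Thinning to the smallest total and leaving out the Gm10800 family were added after seeing the data, and the other alternatives were planned. The cause was not tested for any change below, except where fewer libraries, counts or genes are the alternative itself. Of 4447 values for 290 genes listed for the text, 4078 kept their side of the threshold, 323 lost and 45 gained a call. The remaining 1, of a called gene, reversed direction. A change of direction in a gene called in neither fit was not counted as reversed. Of 1347 values for 85 called lists, 1135 kept direction and side of the threshold, 210 lost the call and 2 reversed. With an estimated correlation 23 of the 85 held, and with fry 51. Counts of genes are followed by higher and lower calls.

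The count for Tregs (2159) stayed within 1.5-fold of itself under all alternatives (1472 to 2587), as did that for day 3 PBS against day 0. Day 1 PBS against day 0 went from 7048 to 4283 (2347 and 1936) with the block and 4230 (2208 and 2022) thinned. Its share of higher calls was 47.5%, and 59.7% without the filter. Day 3 against day 1 PBS went from 4278 to 2585 (1280 and 1305) with the block. Both of these block fits also left out libraries whose number does not recur, so the drops do not measure pairing alone.

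For rIL-17A at day 1, 643 became 1223 (834 and 389) with limma voom, 329 (271 and 58) thinned and 252 to 605 with a library left out. At day 3, 5 became 270 (261 and 9) without the filter, 13 (9 and 4) with DESeq2, 3 (0 and 3) with limma voom, 1 (1 and 0) without the Gm10800 family and 0 to 41 with a library left out. For the difference between days, 76 became 404 (302 and 102) without the filter, 225 (59 and 166) with DESeq2, 220 (76 and 144) with limma voom, 49 (10 and 39) with the block, 139 (60 and 79) in the compared groups only and 14 to 110 with a library left out. Its share of higher calls, 21.1%, was 10.3% with RLE scaling (8 and 70), 36.9% without mitochondrial genes and 37.5% without the Gm10800 family.

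In muscle, 127 became 239 (74 and 165) without the filter, 318 (83 and 235) with limma voom, 229 (49 and 180) with the block and 18 to 401 with a library left out. In liver, 3 became 111 (82 and 29) without the filter, 20 (18 and 2) with DESeq2, 12 (12 and 0) with the block and 0 to 7 with a library left out. For the difference between tissues, 10 became 109 (68 and 41) without the filter, 28 (17 and 11) with DESeq2, 28 (22 and 6) with the block, 5 (3 and 2) thinned and 4 to 21 with a library left out. The set of genes raised by rIL-17A, at an adjusted p of 0.0106 in muscle with limma camera, gave 0.310 with an estimated correlation, 0.389 with fry and 0.000175 to 0.236 with a library left out. The set of lowered genes gave 0.133, and 2.52e-05 without the filter. The correlation of liver and muscle effects, 0.031, ranged from -0.000573 to 0.0523 with a library left out.

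Reversed were Zfp27 (rIL-17A at day 1; log2 change 0.31 thinned, adjusted p = 0.859), the fibre list (rIL-17A at day 1; 0.981 thinned) and the cholesterol synthesis list in liver (0.345 without liver MafΔTreg replicate 3; 3.58e-18 to 0.672 over the libraries left out).

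Replicate numbers may pair the liver samples, as each correlated best with its own number, though the labels do not state pairs. In the other comparisons not every sample did: correlations of equal numbers were 0.0292, -0.0234 and 0.00689 in Tregs, -0.134, 0.0388 and -0.101 at day 1, -0.0829, 0.0664 and -0.0781 at day 3, and 0.0511, -0.00524 and 0.0420 in muscle. There the block ended calls of the heat shock and ribosome lists from day 0 to day 1 (0.161 to 0.198), in a fit with fewer libraries. With rIL-17A at day 1 it ended those of Lum, Fbln1, Col3a1, Ankrd33b, Zfp27 and Mymk (0.0510 to 0.112) and of the glycolysis, differentiation and fibre lists (0.105 to 0.156), and at day 3 those of Gm10718 (0.182) and the ribosome list (0.0839). For the difference between days it ended those of Myod1, Eif4a1, L3mbtl2, Rrp15, Eif5b, Palmd and Traf3ip2 (0.0536 to 0.106). It ended no other call of a list or of a gene listed for the text.

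Depth limits genes with low counts at day 3 with PBS: thinned to 733202 counts, 9181 of 13434 genes passed the filter. Named genes left without a value in thinned MuSCs or tissues include Mrln, S100a2, Cdh4, Cacna2d4, Il1rn, Hp, Ibsp, Cyp1a1, Pdk4, Tnc, Cox8b, Atp1a2, Svep1 and Cidea.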

Other observations

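The tests reported here were chosen before the result was seen. A hypothesis was that rIL-17A moves MuSCs along the course of injury. Across 13434 genes, which are not independent replicates, log2 changes with rIL-17A at day 1 and from day 0 to day 3 PBS, which share no library, had r = 0.0422, against a highest absolute value of 0.124 among the other splits of 10. Those with rIL-17A at day 3 and from day 0 to day 1 PBS had r = 0.0270, against 0.157. Both lie inside the bound of 0.1 set beforehand, but other splits of the same libraries went beyond it. The test therefore cannot decide on such a movement across all genes. A movement of a smaller set of genes is left open too.

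The repeat-like Gm10800 family took 1.28% to 1.41% of counts in day 3 PBS and 0.510% to 0.804% in day 3 rIL-17A MuSCs. In whole muscle its share was 0.0415% to 0.218% in Maf-wt and 0.0119% to 0.0550% in MafΔTreg libraries. Day 3 rIL-17A libraries detected 21363 to 21628 genes and day 3 PBS libraries 14644 to 14990. Thinned to 733202 counts each, they detected 14670 to 15027 and 14422 to 14866.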
